A study of Homo sapiens with 3 samples.

How the data were processed

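Polyadenylated RNA was sequenced from HEK293 cells, a human embryonic kidney line, after 2 h at 40 °C in a water bath. Per the labels, parental cells and 2 LARP7 knockout clones, named 1-11 and 3-6, were used with 2 replicates of each. Cells were grown at 37 °C and seeded 24 h before the heat shock, per the labels' protocols. Nothing in the labels says whether the 2 replicates were separate cultures. LARP7 is a La-related RNA-binding protein best known as a component of the 7SK small nuclear ribonucleoprotein, which holds the elongation kinase P-TEFb inactive, and it also binds the U6 small nuclear RNA of the spliceosome.

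The deposited values form 1 table of alternative splicing events with 4 measured columns. PSI, the proportion of a gene's transcripts that include an exon, intron or splice site, is given by the authors as a fraction from 0 to 1 in steps of 0.01, with 1 pooled value per event for parental cells and 1 for knockout cells. The heading of the knockout column names no clone, so that which clones and libraries went into it is not given in the sources used here. The authors' expected PSI difference is coded as parental minus knockout and was turned into knockout minus parental throughout. It lay within 0.01 of the difference of the PSI columns in every event. The deposited minimum difference is, per the file headers, a value "at 0.9", read here as the size that the absolute PSI difference exceeds with probability 0.9 under the authors' model. It is 0 where no such size is reached and is not corrected for the number of events. The submitters' processing notes name genome build hg38, SAMtools 1.3.1 and R 3.3.3. The aligner and the tool that estimated PSI are not given in the sources used here.

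The table held 70462 events with values, and 8 lines without values were not analysed here. No column gave read counts, coverage, p-values or values per library, and 0 columns of per-sample values were left unused. The depth behind each PSI is therefore unknown, and no interval or detection limit is given for a single PSI. The spread between replicates and between clones could not be computed, and the minimum difference is the only measure of error available for an event.

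An event was called changed where the minimum difference was at least 0.01 and the absolute PSI difference at least 0.1. The PSI threshold was fixed before the data were examined. An adjusted p of 0.05 had been fixed beside it, and because the deposited columns hold no p-value, the minimum difference took its place after the columns had been seen. The planned contrasts of each clone with parental cells, of the clones with each other and of their overlap, and the planned limma model, could not be run on pooled values. Rose and fell refer to called events.

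The share of changed events of each type was compared with that of the remaining events by two-sided Fisher's exact tests. The direction of changed events was tested by two-sided exact binomial tests. Both families were adjusted by Benjamini-Hochberg over 5 event types, and shares carry exact Clopper-Pearson 95% intervals. Events of a gene are not independent, and these tests cover neither the spread between libraries nor the error of a PSI. For 19 gene lists with 1096 genes, fixed before the data were examined, members with a changed event were counted against all genes of the table by two-sided Fisher's exact tests with adjustment over the lists. As genes with more tested events can hold a changed one more often, each list was also compared with 10000 random lists matched in 20 bins of the number of tested events per gene. The random lists were not matched on expression or read depth, which are unknown. This matched test was first computed as one-sided and then made two-sided after its values had been seen, and no list passed either way at the thresholds above.

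The procedures were tested on simulated data with the 70462 real events. With no difference planted, the Fisher test called at least 1 gene list in 24 of 100 runs and the matched test in 0 of 100, so that a Fisher result for a list is read beside its matched one. An 8-fold rate of changed events was planted in the list of mitosis and centrosome genes, 93 of them tested. The matched test called this list in 100 of 100 runs. Smaller lists and lower rates were not simulated. The event type test for retained introns was called in 1 of 100 runs without a difference and in 100 of 100 with one. The direction test was called in 0 and 100 of 100. All runs drew events independently, and those without a difference used a single rate and even directions. They therefore do not cover events of a gene that move together or PSI values too near 0 to fall.

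Gene symbols were updated through the RefSeq gene table, which replaced 762 of 7759 symbols and left 7705 genes. PNISR, SCAF11 and HNRNPDL, for example, are listed there as SFRS18, SFRS2IP and HNRPDL. Coordinates are those of the deposited table, on hg38, 1-based. They were matched exactly to exons and introns of GENCODE release 29 on GRCh38, which gave a match for 99.95% of introns and 85.96% of skipped exons, and for 65.88% of microexons, 59.66% of acceptor sites and 42.37% of donor sites. Named events followed a rule fixed beforehand, except that the event of each gene was taken by the largest minimum difference, in place of the smallest adjusted p that the rule had named. They are the 5 largest rises and 5 largest falls, the largest rise and fall of each event type, and up to 2 members of each list with the largest changes, which gave 34 genes. LARP7 itself was named whatever its result. Outside the rule, after their values were seen, U2SURP, RSRC2, HNRNPH1, RBFOX2, FGFR3 and TMEM63A were named as list members beside a count, and CSTF3, BCAT2, SUN1 and HNRNPH1 for several changed events. ARL6IP4 and UBAP2L were likewise named outside the rule, for their paired donor sites. Some events that the rule or a list gave are not reported here.

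Alternatives dropped the PSI threshold, raised it to 0.2, took 1 event per gene or merged overlapping events. Others, added after seeing the data, required a minimum difference of 0.02 or 0.05 or none, used as background only events with mean PSI from 0.05 to 0.95, or left out introns of the complex class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.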

Results

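Splicing in polyadenylated RNA was compared between parental and LARP7 knockout HEK293 cells, both kept at 40 °C for 2 h. The authors' deposited table gave 1 pooled PSI for each genotype in 70462 splicing events of 7705 genes, made up of 34309 retained introns, 31717 skipped exons, 85 microexons, 2444 alternative acceptor sites and 1907 alternative donor sites. No value per library or clone and no read depth stood beside these PSI values, and no sample without heat shock was among them. The comparisons therefore have no replicate check, and the authors' minimum difference at probability 0.9 is the error measure used for each event.

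LARP7 was listed with 5 skipped exons on chromosome 4, and none of them was called. A coding exon at 112649535 to 112649686 had a PSI of 0.87 in parental and 0.83 in knockout cells, and a coding exon at 112644425 to 112644488 had 0.01 and 0.02. An exon of the 5′ UTR at 112637644 to 112637787 had 0.02 and 0.04. In the authors' deposited table the minimum difference was 0 for all 5. PSI is a proportion among the transcripts present and does not check how much LARP7 RNA the knockout cells held.

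Splicing of 303 events in 251 genes differed between LARP7 knockout and parental cells. Inclusion rose in 121 events and fell in 182. The largest rise was in CCNL2, a cyclin with a role in pre-mRNA splicing, whose 14-nt microexon went from a PSI of 0.46 to 0.89. The largest fall was in LENG8, where retention of 1 intron went from 0.86 to 0.38. Most changed genes held a single changed event (210 of 251), and 41 held 2 or more. The changed events made up 0.43% of those tested, with a median absolute difference of 0.15 and a median minimum difference of 0.03 in the authors' deposited table, and a further 793 events differed by at least 0.1 with a minimum difference of 0. The count depended on the threshold, with 57 events at a PSI difference of 0.2, 79 at a minimum difference of 0.05 and 1096 with no requirement on the minimum difference.

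Further large rises were of different kinds. An alternative acceptor site of SMARCAD1, a chromatin remodelling ATPase, went from 0.26 to 0.6, in a coding exon at chromosome 4, 94278923 to 94279050. A 73-nt exon of CCNL1, a cyclin closely related to CCNL2, went from 0.5 to 0.79 at chromosome 3, 157157011 to 157157083. Like the CCNL2 microexon (chromosome 1, 1392790 to 1392803), it is annotated only in transcripts that are not protein coding. Retention of an intron between coding exons of the phospholipase PLCG1 went from 0.39 to 0.65 at chromosome 20, 41162726 to 41162957. The minimum differences of these 4 events in the authors' deposited table ran from 0.07 for PLCG1 to 0.26 for CCNL2.

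Of the 5 largest falls, 3 were coding exons and 2 were introns between coding exons. The LENG8 intron lies at chromosome 19, 54458522 to 54460765. An intron of CCNT2, a cyclin subunit of the P-TEFb kinase held by the 7SK particle, went from 0.72 to 0.38 at chromosome 2, 134954380 to 134954480. A 90-nt exon of the ubiquitin-conjugating enzyme UBE2B went from 0.98 to 0.62 (chromosome 5, 134380719 to 134380808). A 62-nt exon of TMEM120B went from 0.85 to 0.5 (chromosome 12, 121771488 to 121771549), and a 163-nt exon of the ciliary protein IQCB1 from 0.7 to 0.36 (chromosome 3, 121828470 to 121828632). LENG8 had the highest minimum difference of the authors' deposited table, 0.34, while that of UBE2B was 0.01.

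**Figure D1:**
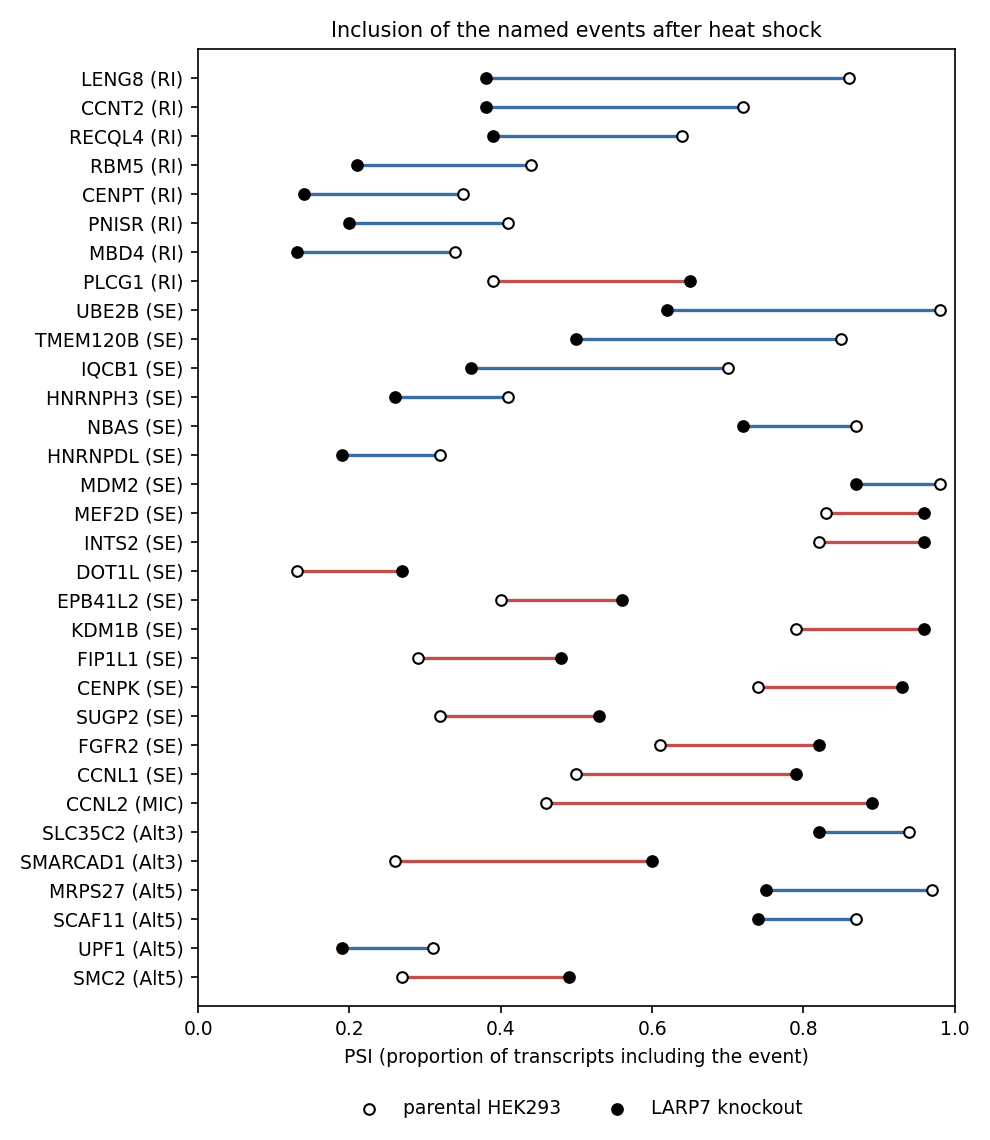
PSI on a scale of 0 to 1 in parental cells (open circles) and LARP7 knockout cells (filled circles) for 32 named events, each the authors' pooled value with no error bar. Lines are red for the 14 events that rose and blue for the 18 that fell, and RI, SE, MIC, Alt3 and Alt5 stand for retained intron, skipped exon, microexon, alternative acceptor site and alternative donor site; of the retained introns shown, PLCG1 rose and LENG8, CCNT2, RECQL4, RBM5, CENPT, PNISR and MBD4 fell.

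Most introns with a called change were retained less in the knockout cells, with 75 of 97 changed introns lower and 22 higher. Retention fell in transcripts of the splicing regulator RBM5 (0.44 to 0.21), the arginine- and serine-rich protein PNISR (0.41 to 0.2), the kinetochore protein CENPT (0.35 to 0.14), the DNA helicase RECQL4 (0.64 to 0.39) and the DNA glycosylase MBD4 (0.34 to 0.13). The minimum difference of the RBM5 and MBD4 introns was 0.01, the lowest that was called. The median PSI of the changed introns was 0.3 in parental and 0.18 in knockout cells. Of the changed introns, 92 lay between coding exons, 2 in 5′ UTRs, 1 in a 3′ UTR and 2 in transcripts not annotated as protein coding. The share that fell was 77.3% (95% interval 67.7 to 85.2%; two-sided exact binomial test, adjusted p = 3.03e-07). That test is against 50%, and uncalled introns with mean PSI of at least 0.05 were themselves lower in 62.9% of cases (odds ratio 2.01 between called and uncalled introns, two-sided Fisher's exact test, p = 0.0029), a comparison limited by the fact that the call selects large differences. Over all 34309 introns the mean PSI was 0.0383 in parental and 0.0368 in knockout cells.

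Skipped exons changed in both directions, with 85 rising and 99 falling. Exons that rose included those of FGFR2, a receptor tyrosine kinase (0.61 to 0.82), CENPK, a kinetochore protein (0.74 to 0.93), and KDM1B, a histone demethylase (0.79 to 0.96). Exons that fell included those of NBAS (0.87 to 0.72) and of MDM2, the ubiquitin ligase of p53 (0.98 to 0.87). Both had a minimum difference of 0.01, the lowest that was called. Most changed exons, 158, were coding, of which 74 rose and 84 fell. The share that fell was 53.8% (46.3 to 61.2%; two-sided exact binomial test, adjusted p = 0.563). Without a requirement on the minimum difference the share was 42.5%, with more exons higher than lower (exact binomial test, adjusted p = 0.000373).

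The kinds of event were not equally represented among the changed ones. Changed events were 0.58% of skipped exons (0.499 to 0.67%) and 0.283% of retained introns (0.229 to 0.345%). Against the remaining events, the odds ratio was 1.89 for skipped exons (two-sided Fisher's exact test, adjusted p = 1.07e-07) and 0.495 for retained introns (adjusted p = 2.22e-08). Donor sites changed in 14 of 1907 events, 7 in each direction, acceptor sites in 7 of 2444, of which 6 rose, and microexons in 1 of 85, with odds ratios of 1.75, 0.657 and 2.76, none of which passed the Fisher's exact test against other events (adjusted p = 0.0815, 0.344 and 0.344). The changed donor sites include a rising and a falling site of ARL6IP4 (0.39 to 0.52 and 0.61 to 0.48). The same holds for UBAP2L (0.22 to 0.33 and 0.78 to 0.66). Such paired sites mirror each other, so that the even split of donor sites is partly built in. They also enter the Fisher's exact tests of donor and acceptor sites as separate events, so that the p-values of these tests may be too small. Among all listed splice sites, 836 share an event number with another listed site. For donor sites, acceptor sites and microexons the result depended on the threshold. With no requirement on the minimum difference the odds ratio turned to 2.29 for acceptor sites and was 2.71 for donor sites and 3.13 for microexons (Fisher's exact test, adjusted p = 1.54e-10, 9.23e-13 and 0.0439). With no PSI threshold it was 0.514 for acceptor sites, 1.73 for donor sites and 4.68 for microexons (Fisher's exact test, adjusted p = 0.034, 0.0193 and 0.034). Donor sites had 2.45 at a minimum difference of 0.02 (Fisher's exact test, adjusted p = 0.00482) and 0.934 at 0.05 (adjusted p = 1.0). Most introns are near a PSI of 0, where a fall of 0.1 is out of reach. Among events with mean PSI from 0.05 to 0.95 the odds ratio was 0.706 for introns (Fisher's exact test, adjusted p = 0.00975), 1.57 for exons (adjusted p = 0.000775) and 0.384 for acceptor sites (adjusted p = 0.00975). This range does not bring the types to equal levels. From 0.05 to 0.1 lay 4458 uncalled introns and 1273 uncalled exons, and from 0.8 to 0.95 lay 38 and 4251. Whether introns changed less often than exons at equal PSI was therefore not tested. At a PSI difference of 0.2 neither introns nor exons stood apart, with odds ratios of 0.823 for introns and 1.18 for exons (Fisher's exact test, adjusted p = 0.724 for both), nor at a minimum difference of 0.05, with 0.645 and 1.54 (adjusted p = 0.152 for both).

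**Figure D2:**
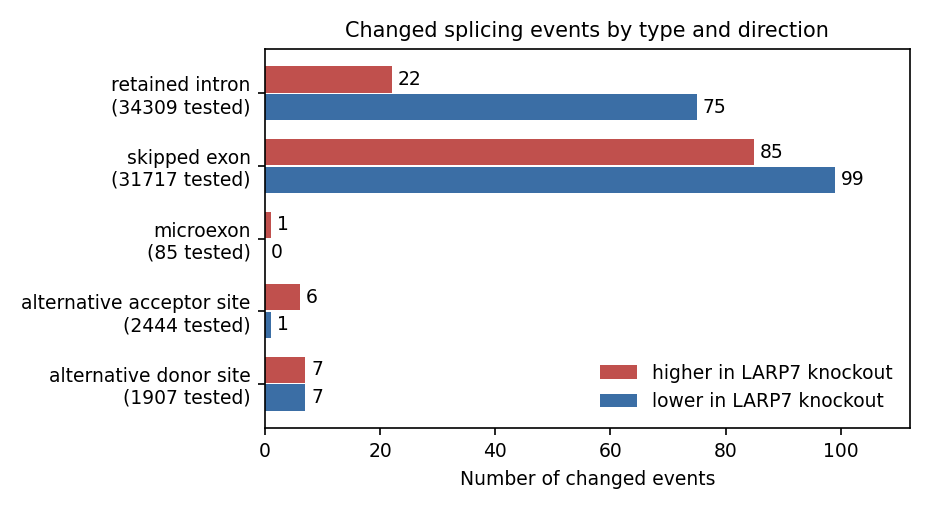
Number of changed events of each type, with red bars for events higher and blue bars for events lower in LARP7 knockout than in parental cells, and the number of events tested under each name. Of the changed retained introns 75 were lower and 22 higher, while skipped exons were split into 99 lower and 85 higher.

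The changes in splice sites included genes of several functions. A donor site of the condensin subunit SMC2 went from 0.27 to 0.49, at position 104094486 of chromosome 9. A donor site of the mitochondrial ribosomal protein MRPS27 went from 0.97 to 0.75 (chromosome 5, 72320149 to 72320191). The largest fall among acceptor sites, the only one of the 7 that fell, was in SLC35C2, from 0.94 to 0.82.

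Genes of the splicing machinery were among the changed ones in small numbers. Of 41 tested genes of the U1 and U2 particles and splice site recognition, RBM5, SUGP2 and U2SURP held a changed event, and inclusion of a SUGP2 exon rose from 0.32 to 0.53. Of 33 genes in the list of SR proteins, related proteins and their kinases, 3 changed, namely PNISR, RSRC2 and SCAF11, the last with a donor site that fell from 0.87 to 0.74. These 3 are related proteins, and no SRSF gene and no kinase of the list held a changed event. Of 49 hnRNP and other splicing regulators, 4 changed, namely HNRNPDL, HNRNPH1, HNRNPH3 and RBFOX2. Exons of HNRNPH3 (0.41 to 0.26) and HNRNPDL (0.32 to 0.19) fell. None of the 34 tested genes of U6 biogenesis and the U4/U6.U5 tri-snRNP and none of the 36 of the later spliceosome held a changed event. The 3 lists with changes had Fisher's exact adjusted p of 0.397, 0.395 and 0.395, and the 2 without changes 0.666 each. With no threshold on the PSI difference, changed events were found in 10 of the 41 U1 and U2 genes and 11 of the 49 hnRNP genes, and both lists passed Fisher's exact test (adjusted p = 0.000823 for both) and the matched permutation test (adjusted p = 0.0456 for both). Neither test accounts for read depth, which may affect how small a difference can be called. With no requirement on the minimum difference neither passed, with 4 U1 and U2 genes against 4.49 expected (odds ratio 0.879, Fisher's exact test, adjusted p = 1.0) and 8 hnRNP genes (odds ratio 1.59, adjusted p = 0.388).

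The lists of genes tied to the heat shock and to translation held no changed event at the thresholds used. This was so for 59 heat shock chaperones and co-factors, 69 cytosolic ribosomal proteins and 59 genes of translation initiation and aminoacyl-tRNA synthesis (Fisher's exact test, adjusted p = 0.421, 0.397 and 0.421). With no PSI threshold the counts were 2, 3 and 4 genes, against 3.42, 4.0 and 3.42 expected. With no requirement on the minimum difference, 1 gene of each list was counted, against 6.46, 7.55 and 6.46 expected (Fisher's exact test, adjusted p = 0.0711, 0.0363 and 0.0711, and matched permutation test, adjusted p = 0.0583, 0.57 and 0.0076). Neither test accounts for read depth, so that a part played by depth in these low counts stays open. Of 21 tested genes around 7SK and P-TEFb, CCNT2 alone held a changed event (adjusted p = 0.666, Fisher's exact test).

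RNA processing and decay factors gave further examples. In nonsense-mediated decay, 2 of 17 genes changed, NBAS and the central helicase UPF1, whose donor site fell from 0.31 to 0.19 (Fisher's exact test, adjusted p = 0.395). Of 34 cleavage and polyadenylation genes, 3 changed (Fisher's exact test, adjusted p = 0.395). A 27-nt exon of FIP1L1, a polyadenylation factor, rose from 0.29 to 0.48, an exon of the Integrator subunit INTS2 rose from 0.82 to 0.96, and the third was CSTF3, a subunit of the cleavage stimulation factor.

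Lists for the cell cycle, the genome, the cilium and cell death each held few changed genes, and none passed the test at the thresholds used. Changed events were found in 4 of 93 genes of mitosis and the centrosome, 4 of 74 of DNA repair, 5 of 94 of chromatin modification, 3 of 46 of the cilium, 1 of 28 of apoptosis and 0 of 14 of telomeres (Fisher's exact test, adjusted p = 0.666, 0.447, 0.421, 0.397, 0.666 and 1.0). With no requirement on the minimum difference, 24 of the 93 mitosis and centrosome genes held a changed event, which passed Fisher's exact test (adjusted p = 0.00117) and the matched permutation test (adjusted p = 0.0076). That setting adds 793 events with a minimum difference of 0, and neither test accounts for read depth. A part played by depth in this result therefore stays open. In the chromatin list an exon of the histone methyltransferase DOT1L rose from 0.13 to 0.27, and in the cilium list IQCB1 held the fallen exon given above.

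Lists of genes known for tissue-type exons were also examined. Of 37 genes with epithelial-type exons, 5 held a changed event, among them FGFR2, FGFR3 and TMEM63A, against 1.21 expected (odds ratio 4.71, Fisher's exact test, p = 0.00655, adjusted p = 0.124, and matched permutation test, adjusted p = 0.939). Of 46 genes with neuronal-type exons, 3 did, namely RBFOX2, the membrane skeleton gene EPB41L2 (0.4 to 0.56) and the transcription factor MEF2D (0.83 to 0.96; Fisher's exact test over the list, adjusted p = 0.397). The lists hold genes, and whether a changed event is the gene's known tissue-type exon was not checked. Of all 19 lists, 0 passed the Fisher's exact test after adjustment and 1, the epithelial one, had an unadjusted p under 0.05, and 0 passed the matched test. The epithelial list passed Fisher's exact test, but not the matched test, at a minimum difference of 0.02 (odds ratio 6.46, adjusted p = 0.0344 and 0.714) and with none required (odds ratio 3.04, adjusted p = 0.0363 and 0.351).

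Below the threshold, differences also leaned one way by type and level. Among uncalled introns with mean PSI of at least 0.05 and a nonzero difference, 62.9% of 5553 were lower in knockout cells (61.6 to 64.2%), with a median difference of -0.01. Among uncalled introns with mean PSI under 0.05, 43.2% of 11867 were lower. Uncalled exons with mean PSI under 0.05 were lower in 20.2% of 2761 cases, and those with mean PSI of at least 0.95 in 63.4% of 11814. Such differences are near the 0.01 step of the deposited PSI, and 40.6% of all events had a difference of exactly 0.

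**Figure D3:**
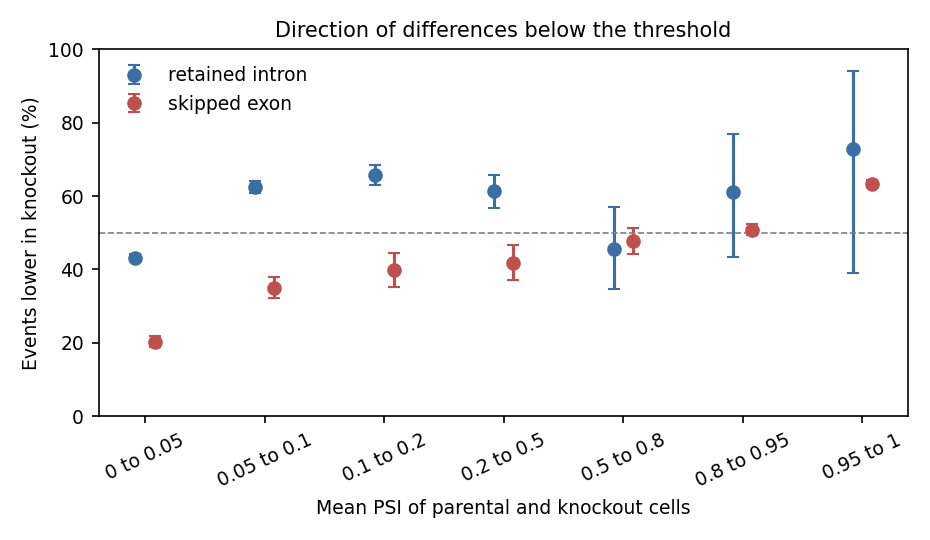
Percent of uncalled events with a nonzero difference that were lower in LARP7 knockout than in parental cells, by the mean PSI of both, for retained introns (blue) and skipped exons (red), with exact 95% binomial intervals over events and a dashed line at 50%. Between a mean PSI of 0.05 and 0.5 introns lie above the line and exons below it, for example 65.8% and 39.8% from 0.1 to 0.2.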

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

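The alternatives on the minimum difference, the background and the complex introns were chosen after seeing the data, the others before. The count of 303 changed events became 549 with no PSI threshold, 57 at 0.2, 79 at a minimum difference of 0.05 and 1096 with none required, by construction of stricter or looser criteria. It stayed within 1.5 times at 220 with a minimum difference of 0.02, 251 with 1 event per gene and 300 with overlapping events merged. The odds ratio of retained introns lost its call at a PSI difference of 0.2 (0.823) and a minimum difference of 0.05 (0.645), as did that of skipped exons (1.18 and 1.54), with fewer events called in both. The share of changed introns that fell was between 75.3% and 90.0% and kept its call in all 7 alternatives. The share of exons that fell was 42.5% with no requirement on the minimum difference, and the cause was not tested. Gene lists passing Fisher's exact test numbered 2 with no PSI threshold, 1 at a minimum difference of 0.02 (the epithelial list, matched permutation adjusted p = 0.714) and 3 with none required (ribosomal proteins with fewer, mitosis and epithelial genes with more; by the matched test mitosis with more and translation genes with fewer, adjusted p = 0.0076 for both), and the cause was not tested. Of the 34 named events, 19 were still called at a PSI difference of 0.2, 25 at a minimum difference of 0.02 and 16 at 0.05. The 9 not called at 0.02 were those of UBE2B, SLC35C2, RBM5, NBAS, INTS2, MBD4, DOT1L, MDM2 and MEF2D.

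No paired analysis was possible because the deposited PSI values are pooled and carry no replicate numbers. For the same reason leaving out a replicate, library or clone and counting splits of the samples were not possible, and the planned coverage filter, adjusted p thresholds of 0.01 and 0.1, limma fits and clone contrasts were not run. Depth is unknown, so that a minimum difference of 0 does not separate an unchanged event from one with few reads.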

Other observations

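Of the tests below, those of the general intron level, of all event types together, of unspliced RNA, of exon blocks, of read support, of the overlap of genes with changed introns and exons and of exons in transcripts that are not protein coding were chosen after the result was seen. The tests of 1 intron per gene, intron length, touching introns and exons, last base, multiples of 3 and GC content were set out before.

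CSTF3, named like BCAT2, SUN1 and HNRNPH1 after its values were seen, held the most changed events of any gene. Its 7 exons all fell by 0.1 to 0.22. An example is a coding exon at chromosome 11, 33102177 to 33102339, from 0.93 to 0.71, with a minimum difference of 0.01. Sets of 3 changed exons in the same direction were also listed for BCAT2, which fell, and for CENPK and SUN1, which rose. Genes with a changed intron and a changed exon numbered 9 against 2.08 expected (odds ratio 4.98, two-sided Fisher's exact test, p = 0.000206), and among them were the cyclin CCNL1 and the splicing regulators HNRNPH1 and RBM5. In HNRNPH1 retention of 2 introns fell (0.36 to 0.26 and 0.19 to 0.08) while a 50-nt coding exon rose from 0.58 to 0.68. In 0% of these 9 genes (95% interval up to 33.6%) did the changed intron and exon touch at their edges. A change listed under both types at a shared edge therefore does not account for the overlap. An exon inside the intron or farther off was not looked for, so that other double listings stay open. The larger number of tested events in some genes was not tested either.

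The fall of retained introns was weighed against explanations in the values themselves. It did not rest on a few genes, as 77.4% of introns fell with 1 intron per gene (67.0 to 85.8%), nor on a lower level of all event types, as 53.8% of changed exons fell. A lower intron signal in general is open and may account for part of it, since 62.9% of uncalled introns with mean PSI of at least 0.05 were lower, by a median of -0.01. Less unspliced RNA or genomic DNA in the knockout libraries cannot be told apart from a change in splicing, because the 43.2% of introns under a PSI of 0.05 that were lower lie in a range where exons also went up. Loss of LARP7, the biological explanation given by the design, stays open as untested against differences between clones or libraries.

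Uncalled exons of low PSI and those nearest to 1 lay closer to the middle of the scale in the knockout values, with 20.2% of those under a mean PSI of 0.05 lower and 63.4% of those of at least 0.95. Exons from 0.05 to 0.1, 0.1 to 0.2 and 0.2 to 0.5 were also mostly higher, with 34.9%, 39.8% and 41.8% lower. Exons in the upper middle did not follow, as 47.8% were lower from 0.5 to 0.8 (44.3 to 51.2%) and 50.9% from 0.8 to 0.95 (49.3 to 52.4%). Fewer reads behind the knockout values could give these shifts if estimates are drawn toward the middle where reads are few, but the values from 0.8 to 0.95 go against such a pull on all exons as the whole cause. Introns with mean PSI from 0.1 to 0.5 went the opposite way, 64.6% being lower (62.2 to 66.8%), but introns had a fall of their own. The labels list 2 replicates of each of 2 knockout clones and 2 of parental cells. If all were pooled, more libraries stood behind the knockout values, but their depth is unknown. Without read counts a part played by read support cannot be told apart from an effect of LARP7 loss, which was not tested.

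Changed exons of the same gene shared a direction in 93.2% of 44 pairs (one-sided permutation p = 0.0001, the smallest that 10000 permutations can give), and 15 of 18 such genes moved one way. They were neighbours among the tested exons of their gene 17 times against 8.26 for random places (one-sided permutation p = 0.0002). Both are consistent with neighbouring exons included or skipped as a block, although joint inclusion in 1 transcript was not measured. CSTF3 alone supplied 21 of the 44 pairs, and without it 87.0% of 23 pairs shared a direction (one-sided permutation p = 0.0004) and 14 neighbours stood against 5.59 (p = 0.0001 by permutation).

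Properties of the changed sequences gave no difference past a threshold. Introns that fell had a median length of 246 nt. Random draws from the fallen and uncalled introns together, matched on parental PSI, had 253 nt (two-sided permutation p = 0.941). The last base was G in 80.5% of exons that rose and 77.3% of exons that fell (Fisher's exact p = 0.708), and the length was a multiple of 3 in 45.1% of changed and 42.0% of uncalled alternative exons (Fisher's exact p = 0.407). Exons that rose had a mean GC content of 50.7% and exons that fell 47.5% (two-sided permutation p = 0.0554). Exons annotated only in transcripts that are not protein coding rose in 8 cases and fell in 3, against 74 and 84 for coding exons (two-sided Fisher's exact p = 0.124).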
